A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

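Transcript levels of budding yeast (Saccharomyces cerevisiae) were measured on 12 Affymetrix yeast expression arrays, each hybridised with labelled RNA of 1 culture sample. The strain was BY4741, a haploid laboratory strain of mating type a, either wild type or deficient in SLT2. SLT2 encodes the mitogen-activated protein kinase of the cell wall integrity pathway, a signalling route that responds to damage of the cell wall. Cells growing exponentially in rich medium (YEPD) at 30 °C were sampled untreated, at 0 minutes, or after 2 h with 100 µM sodium arsenate, a toxic analogue of phosphate. The labels give 4 groups of 3 replicates. The submitters' design text calls the replicates independent and does not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Treated cells had also grown for 2 h longer than untreated cells, and no untreated sample of 2 h was analysed here, so arsenate and culture time are confounded in each arsenate effect.

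The deposited values are log2 signals summarised per probe set with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set. Its versions and settings are not given in the sources used here. The log2 scale was read from the values, which ran from 3.05 to 14.91, and the median of an array lay between 9.98 and 10.20. Values of the wild-type arrays carry up to 8 significant digits and those of the slt2 arrays up to 7. Whether all 12 arrays were summarised in 1 RMA run is not given in the sources used here. Scanner files were not used here. For arrays the number of replicates limits the precision.

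The table holds 5814 probe sets. Of these, 98 were control or reporter probe sets. The platform annotation gives 1 gene symbol for 5498 probe sets, several for 0 and none for 316, the controls included. All 5498 were matched to a table of reference genes by gene number and took their current symbols from it. For the 47 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays was kept, which left 5449 genes for testing. Between probe sets of 1 gene the arsenate effect in slt2 differed by at most 0.30 log2 units.

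A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, no replicate term). It gave 5 comparisons: the arsenate effect in wild type, the arsenate effect in slt2, slt2 against wild type without arsenate, the same with arsenate, and the difference of the arsenate effects, slt2 minus wild type. P-values were adjusted by the Benjamini-Hochberg method over the 5449 genes, with a threshold of 0.05. Called genes are those past this threshold. The model on the 6 arrays of the groups compared was an alternative chosen before the data were examined. In the slt2 arrays it called many more genes than the 12-array model, and it was made a result of its own after those calls were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

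Before the data were examined, 30 gene lists were fixed. They cover arsenic handling, phosphate, sulfur, stress, the cell wall, ribosomes, metabolism, the cell cycle, mating type and strain markers. The 28 lists with at least 5 measured members were tested with limma's camera, which asks whether a list's genes shifted against all other genes, at a preset correlation of 0.01 between members. Its p-values were adjusted over the 28 lists. Camera was repeated with a correlation estimated from the arrays, and fry, which tests whether a list's genes move one way on balance, was run beside it. For each list the calls were also counted with p-values adjusted over the list alone. Genes were named by a rule fixed at the same time. It takes SLT2 and the strain markers, up to 12 genes with the largest rise and up to 12 with the largest fall among called genes whose groups did not overlap, and up to 4 called members of each list described. It also takes ARR1, ARR2, ARR3, YCF1, FPS1 and PHO84 for the arsenate effects. For the difference of effects it takes the 5 genes with the smallest p where fewer than 3 pass. Other genes named here were chosen after their values were seen, and are given as such.

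The model was tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units among 5449. With 1 spread per gene in all groups, false calls made up between 2.99% and 9.21% of the calls. With the spread each group really had, false calls in the 12-array model made up 64.6% of the calls of the wild-type arsenate effect, 59.8% for slt2 against wild type with arsenate and 30.5% for the difference. The share was 0% for the arsenate effect in slt2 and 6.02% for the untreated genotypes. For the model on the slt2 arrays alone it was 7.66%, and 95% of the genes changed by 1 log2 unit were recovered. Noise was drawn independently for each gene. Deviations that many genes share on 1 array, as seen on wild-type arrays, were thus not simulated, and these shares need not hold for the data.

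Alternatives were the model on the 6 arrays compared, the replicate number as a block, a trended and robust prior, centring each array on its median, quantile normalization over the tested probe sets, the mean of a gene's probe sets, all probe sets but controls, the dimmest 20% of probe sets left out, array weights, an adjusted p of 0.01 and each array left out in turn. After the data were seen, 1 weight per group was added, as was a run without 3 wild-type arrays that stood apart (untreated array 2 and arsenate arrays 1 and 2). No columns of the table were left out.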

Results

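The data are log2 signals of 5449 yeast genes on 12 arrays. Wild-type BY4741 cells and cells deficient in the kinase Slt2 were each sampled untreated and after 2 h with 100 µM sodium arsenate, with 3 arrays in each of the 4 groups. Levels are given as mean ± SD of the 3 arrays of a group on the log2 scale, and changes as log2 fold changes with their standard error (SE). An array has no count depth, so the number of arrays sets the precision.

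SLT2 (locus YHR030C) checked the genotype labels. Its signal was 10.76 ± 0.11 (SD, n = 3) in untreated and 10.96 ± 0.05 in arsenate-treated wild type, against 5.56 ± 0.26 and 5.55 ± 0.30 in the slt2 groups. The 6 wild-type arrays lay between 10.66 and 11.01 and the 6 slt2 arrays between 5.22 and 5.81. Genes deleted in BY4741 gave the background on the same arrays: LEU2, URA3 and MET17 lay between 3.74 and 5.47 on all 12 arrays. The level of SLT2 in the slt2 arrays was thus close to the signal of absent transcripts. HIS3 lay between 10.58 and 12.21, and since the HIS3 deletion of this strain is partial, its probe set checks nothing. Strain and genotype labels were therefore not contradicted by any array.

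**Figure D1:**
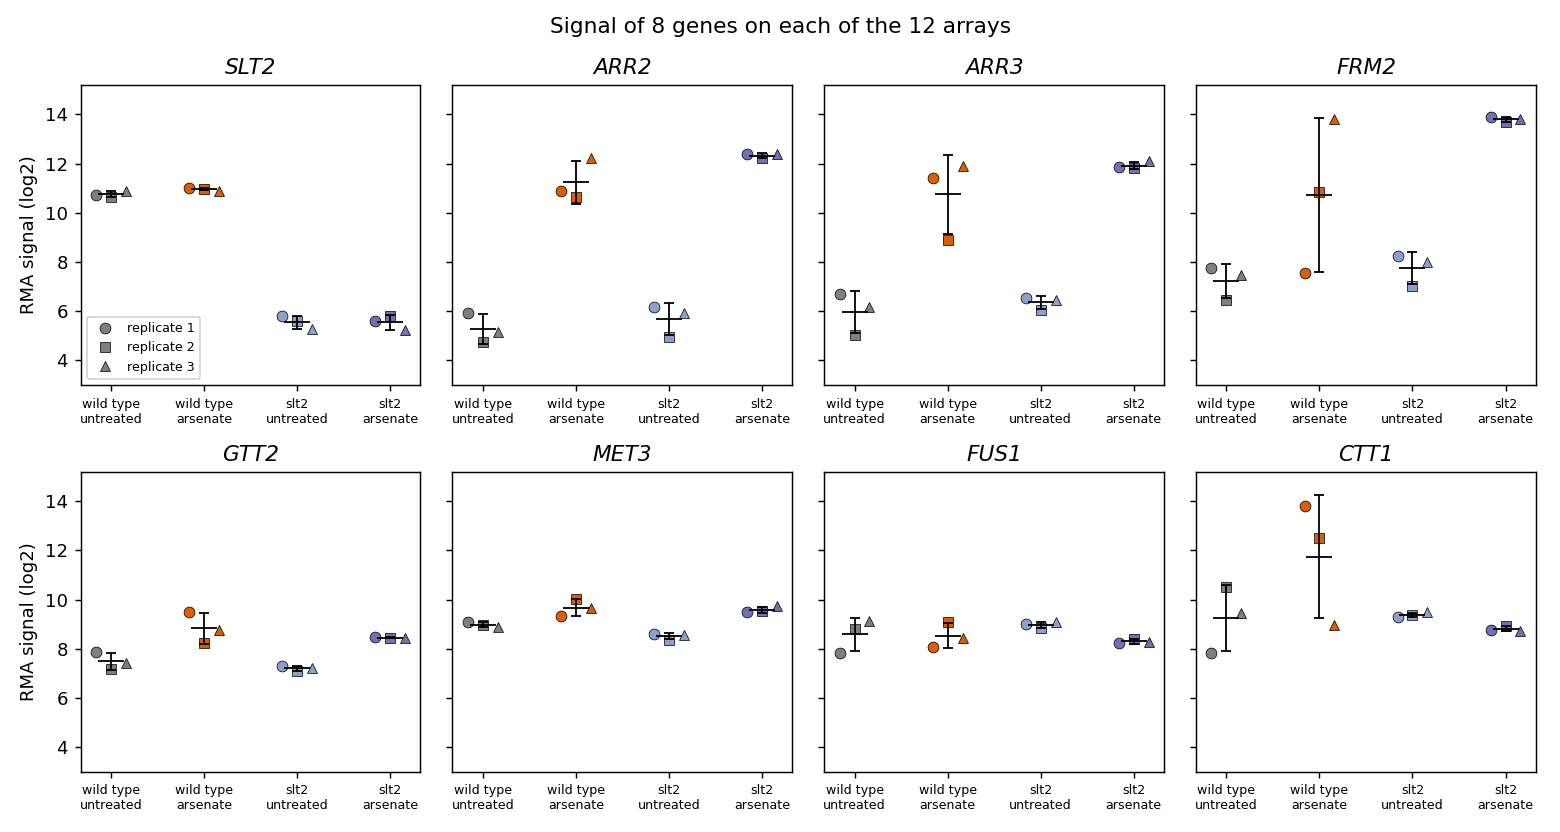
RMA signal (log2, vertical axis) of SLT2, ARR2, ARR3, FRM2, GTT2, MET3, FUS1 and CTT1 in the 4 groups (horizontal axis), with 1 point per array, the marker shape giving the replicate number, the horizontal bar the mean and the error bar the SD of 3 arrays. SLT2 lies between 5.22 and 5.81 on the slt2 arrays and at 10.66 or above on the wild-type arrays, and ARR2 and ARR3 lie higher on every arsenate array than on any untreated one.

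The wild-type arrays differed among themselves far more than the slt2 arrays did. The median SD of a gene was 0.21 in untreated and 0.49 in arsenate-treated wild type, against 0.08 and 0.07 in the slt2 groups. Wild-type untreated array 3 correlated with its replicates at r = 0.973 and 0.984 across genes, and with slt2 untreated arrays at 0.993 or higher. For wild-type arsenate array 3 these values were 0.672 and 0.949, and at least 0.9896 with slt2 arsenate arrays. The other wild-type arrays were not closer to slt2 in this way. Such correlations do not test for offsets between the genotypes. Wild-type arsenate array 1 correlated with the other 11 arrays at r from 0.621 to 0.779 across genes, whereas replicate arrays within each slt2 group correlated at 0.996 to 0.998. On that array the glucose-repressed genes, which yeast turns on when glucose runs out, had a median 4.87 log2 units above the mean of wild-type untreated arrays 1 and 3. The same reference is used for the medians that follow. Ribosome biogenesis genes had a median of -3.74 and cytosolic ribosomal protein genes of -2.16 on it. The general stress list had a median of 4.33 on wild-type arsenate array 1, 2.71 on arsenate array 2, 0.41 on arsenate array 3 and 1.34 on untreated array 2. On the slt2 arrays it lay between -0.07 and 0.39. A measure of RNA quality, the 3' minus 5' signal averaged over 7 control transcripts, was 1.59 on wild-type untreated array 2 and 1.79 on wild-type arsenate array 2, and between 0.92 and 1.18 on the other 10 arrays.

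**Figure D2:**
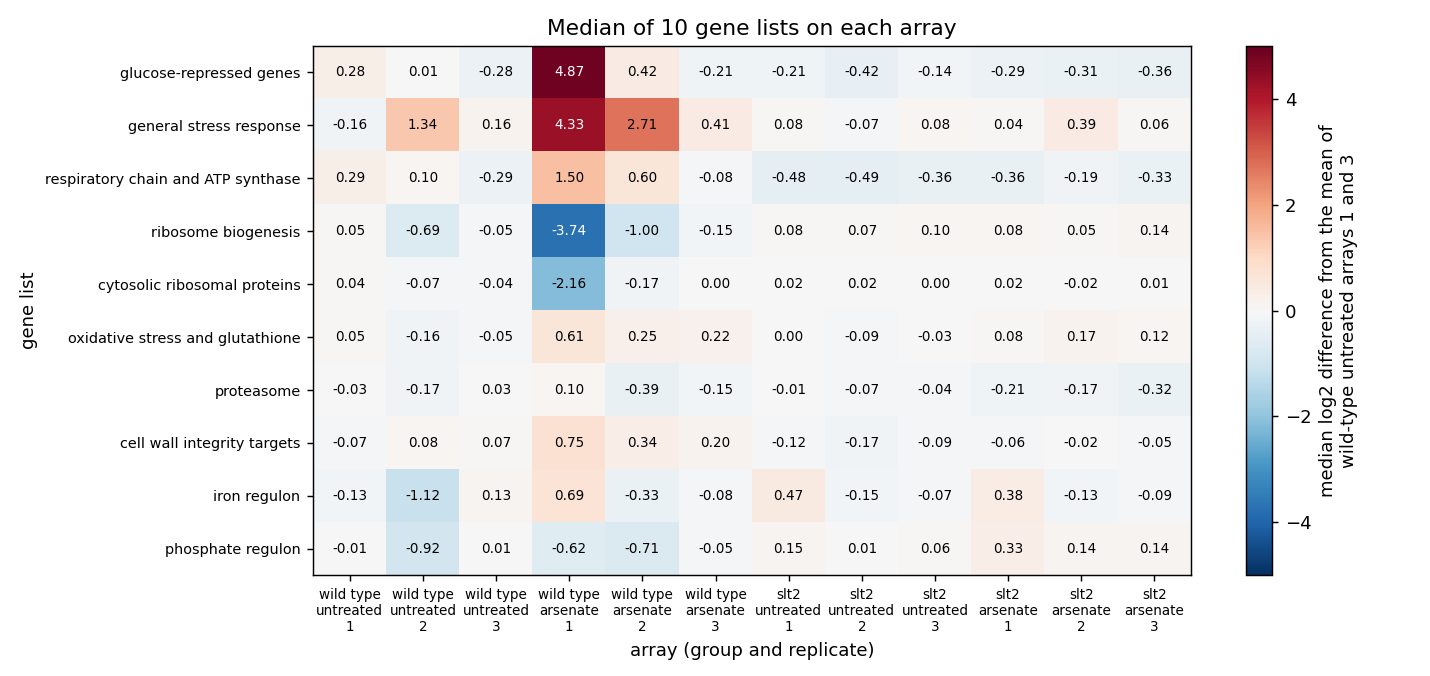
Median log2 difference of 10 gene lists (vertical axis) on each of the 12 arrays (horizontal axis, group and replicate), taken against the mean of wild-type untreated arrays 1 and 3; colour and printed number give the same value. Wild-type arsenate array 1 stands out, with 4.87 for glucose-repressed genes and -3.74 for ribosome biogenesis.

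The first comparison asked which transcripts differ in wild-type cells after 2 h with arsenate. The arsenate reductase gene ARR2 (locus YPR200C) rose from 5.28 ± 0.61 to 11.25 ± 0.87 (log2 fold change 5.97, SE 0.46, adjusted p = 0.000843). It was higher on 3 of 3 arsenate arrays. Its mean untreated signal was no higher than that of deleted genes (up to 5.47), so the size of the rise is poorly resolved. The neighbouring gene ARR3 (YPR201W), which encodes the plasma membrane pump that exports arsenite, went from 5.97 ± 0.85 to 10.75 ± 1.61, a log2 fold change of 4.77 that missed the threshold (SE 0.68, adjusted p = 0.0738) and whose size is poorly resolved too, since the untreated mean lay within its SD of the level of deleted genes. The side of the threshold on which ARR3 fell depended on the model. It passed with the replicate block (adjusted p = 0.039), while its highest adjusted p over the alternatives was 0.631. Over the arsenic list alone, adjustment called ARR2 and ARR3 higher and FPS1, the glycerol channel through which arsenite enters, lower (log2 fold change -0.38). The other genes of arsenic handling did not pass. The log2 fold change was 0.39 for the regulator gene ARR1, 0.12 for the vacuolar transporter gene YCF1 and -1.46 for the phosphate carrier gene PHO84, through which arsenate enters (adjusted p = 0.318, 0.495 and 0.3).

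Several gene groups moved in wild type according to camera. The oxidative stress and glutathione list shifted up, with a median of 0.40 over 28 genes, 24 of them above 0 (adjusted p = 5.43e-06, and 0.63 with an estimated correlation). On the wild-type arsenate arrays its median was 0.61, 0.25 and 0.22. Adjusted over the list alone, 3 members were called higher: GRE2, GTT2 and OYE3, with log2 fold changes of 1.63, 1.35 and 2.34. They encode a methylglyoxal reductase, a glutathione transferase and an NADPH oxidoreductase, and they are named after their values were seen, as are MET3 and MET13. These enzymes of sulfate activation and methyl group supply were the calls adjusted over the sulfur list alone, with log2 fold changes of 0.69 and -0.75. The list of targets of the cell wall integrity pathway shifted up with a median of 0.39 (adjusted p = 0.0142, and 0.63 with an estimated correlation). On the wild-type arsenate arrays its median was 0.75, 0.34 and 0.20. None of its 20 members passed, adjusted over all genes or over the list alone.

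The largest list shifts in wild type were strongest on arsenate array 1. The general stress list had a median of 1.93 with 31 of 31 members above 0 (adjusted p = 1.58e-09), the glucose-repressed list one of 1.79 (adjusted p = 0.0013), the respiratory list one of 0.62 and the tricarboxylic acid cycle list one of 0.66 (adjusted p = 8.28e-08 and 0.000169). Ribosome biogenesis had a median of -1.38 with 65 of 65 members below 0 (adjusted p = 5.68e-16), and RNA polymerases I and III one of -1.01 (adjusted p = 8.83e-07). The median was -0.76 for cytosolic ribosomal proteins, -0.50 for amino acid synthesis and -0.38 for ergosterol synthesis (adjusted p = 1.33e-17, 5.43e-06 and 0.000173). The median was below 0 for late G1 genes (-0.56), histones (-0.22), the proteasome (-0.09) and cell wall synthesis (-0.25) and above 0 for cell separation (0.40) and meiosis genes (0.53), with camera adjusted p between 0.00128 and 0.0242 and no member called. With an estimated correlation the smallest adjusted p of the 28 lists was 0.63, so none of these 17 calls held. Without the 3 wild-type arrays that stood apart, a run added after the data were seen that keeps 1 arsenate array and assumes that it varies like the other groups, the medians were -0.21 for glucose-repressed genes, 0.41 for general stress, -0.15 for ribosome biogenesis and 0.22 for the oxidative list (adjusted p = 0.243, 4.82e-07, 3.95e-11 and 5.14e-10). They were 0.20 for the cell wall integrity targets, -0.11 for RNA polymerases I and III, 0.08 for the tricarboxylic acid cycle, -0.08 for histones, 0.19 for cell separation and -0.15 for the proteasome (adjusted p = 0.0181, 0.0119, 0.0478, 0.212, 0.00237 and 2.31e-08). In that run 8 of the 17 medians changed sign: those of glucose-repressed genes, late G1 (0.12, which passed upward, adjusted p = 0.00762), meiosis (-0.13), respiration (-0.08), ribosomal proteins, amino acid synthesis, ergosterol and cell wall synthesis (each between 0 and 0.02). The other 11 lists, from phosphate (median -0.37, adjusted p = 0.277) to iron (0.39, 0.0678, and 0.049 and 0.0388 with centred and quantile-normalised arrays), did not pass. The mean, the median and camera differed in sign for arsenic (mean 0.77, median -0.20, up), sulfur (mean -0.11, median 0.15, up), glycolysis and a-cell genes, none of which passed. Of the alpha-cell genes, too few to test as a list, 1 was higher adjusted over the list alone. No list that passed in any comparison changed the sign of its median when arrays were centred or quantile-normalised, though cell wall synthesis, histones and meiosis no longer passed with quantile normalization here (adjusted p = 0.0808, 0.0628 and 0.0628).

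In wild type limma called 1 gene higher and 0 lower over all 5449, while 696 genes had an unadjusted p under 0.05. The groups did not overlap for 8.57% of the genes, where chance gives 10% for groups of equal spread. These groups differed in spread (median SD 0.21 untreated and 0.49 with arsenate). On simulated data with each group's own spread and noise independent between genes, 64.6% of the calls of this comparison were false. The simulation made 426 calls where the data gave 1, so this share need not hold for the data. ARR2 lost its call in the model on the 6 wild-type arrays and with 1 weight per group (adjusted p = 0.144 and 0.587, in a range from 0.000352 to 0.587 over its alternatives), and 812 genes higher and 796 lower were called without wild-type arsenate array 3, 2 higher without arsenate array 2, and 3 (ARR2, ARR3 and FRM2) without the 3 arrays that stood apart.

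The second comparison asked which transcripts differ in slt2 cells after arsenate. ARR2 rose from 5.68 ± 0.65, within its SD of the level of deleted genes (up to 5.47), to 12.33 ± 0.09, so that the size of the rise is again poorly resolved (log2 fold change 6.65, SE 0.46, adjusted p = 0.000304), and ARR3 rose 47.1-fold, from 6.36 ± 0.27 to 11.92 ± 0.15 (log2 fold change 5.56, SE 0.68, adjusted p = 0.0267). These were the only genes called by limma in the 12-array model, 2 higher and 0 lower, with 71 genes at an unadjusted p under 0.05. The ARR3 call was lost when any of the 6 slt2 arrays, wild-type untreated array 1 or wild-type untreated array 3 was left out (adjusted p from 0.0548 to 0.225, in a range from 1.26e-11 to 0.225 over its alternatives). The spread in that model comes largely from the wild-type arrays, and groups did not overlap for 22.6% of the genes where chance gives 10%.

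Fitted to the 6 slt2 arrays alone, the model called 104 genes higher and 30 lower, 20 and 1 of them by at least 1 log2 unit. Many of these calls depended on the model: with the replicate number as a block, 26 of the 45 called genes that were named lost their call. The values that follow come from the fit to the 6 arrays without a block. Of the 10 genes of arsenic handling, 4 rose and 0 fell, adjusted over all genes or over the list alone. ARR2 and ARR3 rose as above, with SE 0.30 and 0.14 (adjusted p = 0.000313 and 2.44e-05). The regulator gene ARR1 rose by 0.35 (SE 0.05, adjusted p = 0.023) and YCF1, whose product moves glutathione conjugates of arsenic into the vacuole, by 0.27 (SE 0.05, adjusted p = 0.0414). FPS1 and PHO84 did not pass (log2 fold change -0.04 and 0.09, adjusted p = 0.785 and 0.595). The list had a median of 0.17 (camera adjusted p = 0.000993, and 0.596 with an estimated correlation).

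Genes of oxidative defence and detoxification were among those that rose in slt2. The second largest rise was that of FRM2, a nitroreductase-like gene, which went from 7.76 ± 0.66 to 13.80 ± 0.10 (66-fold, log2 fold change 6.04, SE 0.30, adjusted p = 0.000379). Of the 28 genes of oxidative stress and glutathione, 10 rose and 0 fell, and adjusted over the list alone 15 rose and 1 fell. Examples were OYE3 (log2 fold change 1.42), GTT2 (1.25), GRE2 (1.17) and the drug efflux gene ATR1 (1.16), with SE from 0.06 to 0.17 and adjusted p from 0.000379 to 0.023. The list median was 0.22 (camera adjusted p = 2.8e-07, and 0.575 with an estimated correlation). It also passed fry (adjusted p = 0.0131), as 1 of 3 lists in this fit, where camera passed 12. Outside the lists, the oxidoreductase gene YNL134C rose by 1.62, the glyoxalase gene HSP31 by 1.46, the stress gene DDR48 by 1.24 and HBN1, a relative of FRM2, by 1.24 (adjusted p from 0.00148 to 0.0135). ZPS1, which encodes a zinc-regulated secreted protein, rose 6.29-fold from 10.51 ± 0.18 to 13.16 ± 0.25 (adjusted p = 0.000583).

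Sulfur assimilation split within its list. Of 27 genes, 6 rose and 2 fell, and adjusted over the list alone 11 rose and 4 fell. MET2, MET3, MET10 and MET14, enzymes of homoserine acetylation and of sulfate activation and reduction, rose by 1.34, 1.07, 0.99 and 0.70 (SE 0.19, 0.09, 0.10 and 0.07). MET13, the methylenetetrahydrofolate reductase gene, fell by 0.69 (SE 0.11, adjusted p = 0.0277) and SAM2, an S-adenosylmethionine synthetase gene named after its value was seen, by 0.27 (adjusted p = 0.0334). The list median was 0.15 (camera adjusted p = 0.00226, and 0.713 with an estimated correlation). The phosphate list had a median of 0.09 and passed camera (adjusted p = 0.0467, and 0.842 with an estimated correlation). Of its 16 genes PHO5, a secreted acid phosphatase gene, was called, and rose by 0.91 (SE 0.05, adjusted p = 0.000599). Respiratory genes, with a median of 0.16 and 33 of 35 above 0, and tricarboxylic acid cycle genes, with 0.17 and 11 of 11, passed as lists (adjusted p = 8.79e-05 and 0.000804, and 0.727 and 0.596 with an estimated correlation). No member of either was called over all genes, and 3 of the cycle were adjusted over the list alone.

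Mating, proteasome and chaperone lists were lower in slt2 against other genes, with few single genes called. Of 20 pheromone response genes 5 fell and 0 rose, 7 adjusted over the list alone, among them FUS1 of cell fusion (-0.68), the agglutinin gene AGA1 (-0.61), SST2 (-0.46) and FAR1 (-0.42). Of 7 genes specific to a cells 3 fell, 6 adjusted over the list alone: the pheromone gene MFA1 (-0.61), AGA2 (-0.51) and the pheromone protease gene BAR1 (-0.38). Their list medians were -0.17 and -0.38 (camera adjusted p = 7e-08 and 6.52e-10). Proteasome genes shifted little: the median was -0.19, 32 of 32 lay below 0 and 28 fell adjusted over the list alone, while PUP1 (-0.26, adjusted p = 0.0414) was called over all genes (camera adjusted p = 7.26e-24). Heat shock and folding genes had a median of -0.21, with 11 of 26 lower adjusted over the list alone and AHA1, a co-chaperone gene of Hsp90, lower over all genes (-0.35, adjusted p = 0.0158; camera adjusted p = 1.26e-11). Late G1 genes (median -0.09, 0 of 26 called, camera adjusted p = 8.47e-07) and cytosolic ribosomal proteins (-0.02, 0 of 128, 0.000445, and 0.749 after quantile normalization) also passed as lists. With an estimated correlation the adjusted p was 0.713 for ribosomal proteins and 0.575 for each of the other 5 lists in this paragraph. In the 12-array model the pheromone list was the 1 of 10 lists past the threshold whose call held with an estimated correlation (adjusted p = 0.0308). In that model ribosomal proteins did not pass with centred or quantile-normalised arrays (adjusted p = 0.27 and 0.731), while amino acid synthesis, cell wall integrity targets, general stress, phosphate and respiration passed with quantile normalization only (adjusted p from 0.0089 to 0.0244).

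The largest falls in slt2 were those of the metalloreductase gene FRE7 (-1.06, SE 0.10, adjusted p = 0.00576), YMR206W (-0.81) and the mitochondrial gene FMP16 (-0.75). The cell wall mannoprotein gene TIR1 fell by 0.62. Of 31 general stress genes 0 rose and 4 fell over all genes: TKL2 (-0.62), GND2 (-0.61), the catalase gene CTT1 (-0.57) and DCS2 (-0.40). Adjusted over the list alone 12 rose and 5 fell, the list median was 0.25, and camera did not pass (adjusted p = 0.167), though it passed upward with centred arrays (0.0345) and with quantile normalization (0.0331). Among cell wall integrity targets 2 of 20 rose, the glucan synthase gene GSC2 by 0.89 (SE 0.08, adjusted p = 0.00421) and the wall protein gene SED1 by 0.35 (SE 0.06, adjusted p = 0.0379), 5 adjusted over the list alone. The list did not pass (median 0.05, adjusted p = 0.125). The sensor gene MTL1 of the pathway rose by 0.68 (adjusted p = 0.0452), as did ENO1 of glycolysis by 0.52, SPS4 of sporulation by 0.70 and PRY3 by 0.36, the single calls of their lists. The lists of pathway components, cell wall synthesis, ribosome biogenesis, RNA polymerases, iron, glucose-repressed genes, glycolysis, ergosterol, amino acid synthesis, the unfolded protein response, histones, G2 and M phase, cell separation and meiosis did not pass (adjusted p from 0.0534 to 0.8). Among these, medians of pathway components, cell wall synthesis, ribosome biogenesis, RNA polymerases, glucose-repressed genes, glycolysis and cell separation lay within 0.04 of 0 and changed sign with the scaling of the arrays. Ergosterol passed downward with centred arrays (adjusted p = 0.0213) and amino acid synthesis upward with quantile normalization (adjusted p = 0.0113). Alpha-cell genes and strain markers, with 4 members each, were too few to test as lists, and 0 of them were called.

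Of the 134 calls in the slt2 arrays, 77.6% were rises. Centring the arrays on their medians gave 158 rises and 84 falls (65.3% rises) and quantile normalization 184 and 157 (54%). Of the 134 genes, 131 and 126 were among these calls. Leaving out slt2 untreated array 1, 2 or 3 gave 89, 107 and 41 calls and leaving out arsenate array 1, 2 or 3 gave 53, 46 and 79. Of the 134 genes, 76, 89, 40, 47, 44 and 63 were still called, in the same order.

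The genes called in the slt2 arrays were then looked up in the wild-type arrays, which are separate samples; this comparison was chosen after the calls were seen. The genes that rose in slt2 were mostly higher in arsenate-treated wild type. Of the 104 genes, 73, 87 and 96 were higher on wild-type arsenate arrays 1, 2 and 3 than in the untreated mean, and as a set they rose by a mean of 0.85 log2 units (median 0.69; camera p = 7.88e-15, and 0.000664 with an estimated correlation). For 26 of them (25%) all 3 arsenate arrays lay above all 3 untreated arrays, against 5.65% of all genes. Chance gives 5% for groups of equal spread. The 30 genes that fell in slt2 behaved less evenly: 18, 16 and 27 were lower on arsenate arrays 1, 2 and 3. Their mean in wild type was 0.20 and their median -0.15, and camera put them down against other genes (p = 0.0483, and 0.182 with an estimated correlation), so that mean, median and test differ in sign. Without the 3 wild-type arrays that stood apart the mean was -0.25. CTT1, FRE7 and TKL2 belong to these 30, and the general stress list to which CTT1 and TKL2 belong was at 4.33 and 2.71 on arsenate arrays 1 and 2.

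Over the 134 genes together, the change in slt2 correlated with that on each wild-type arsenate array at r = 0.226, 0.477 and 0.947 for arrays 1, 2 and 3 (rho 0.208, 0.373 and 0.810). These are correlations across genes, which are not independent replicates, and the genes were chosen for their change in slt2. Over all 5449 genes the mean effects in wild type and slt2 correlated at r = 0.374 (rho 0.425, jackknife SE over arrays 0.242). By wild-type array r was 0.232, 0.355 and 0.639, and rho 0.364, 0.341 and 0.379, so by rank the 3 arrays differed little. With 1 array left out, the correlation of the mean effects was highest without wild-type arsenate array 1 (0.577) and lowest without arsenate array 3 (0.292). Without the 3 arrays that stood apart it was 0.684. Single genes called in slt2 and read on the wild-type arrays spread widely: FRM2 was at 7.55, 10.84 and 13.80 on arsenate arrays 1, 2 and 3, and at 6.47 to 7.75 untreated.

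**Figure D3:**
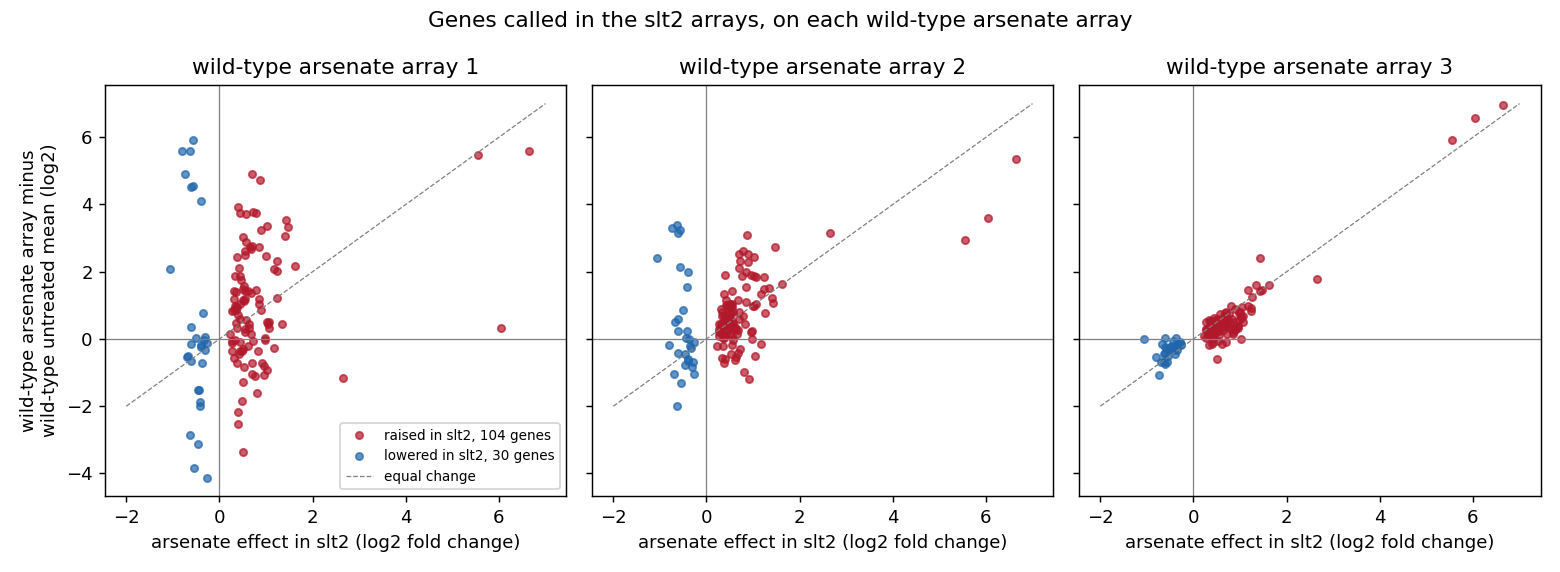
Arsenate effect in slt2 (log2 fold change, horizontal axis) of the 104 genes that rose and the 30 that fell in the slt2 arrays, against their difference from the wild-type untreated mean (log2, vertical axis) on wild-type arsenate arrays 1, 2 and 3. Each point is 1 gene and the dashed line marks equal change; the points lie along it on array 3 (r = 0.947) and scatter on array 1 (r = 0.226).

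The third comparison asked how untreated slt2 cells differ from untreated wild type. Beside the loss of SLT2 itself (log2 fold change -5.20, SE 0.18, adjusted p = 2.55e-07), limma called 0 genes higher and 1 lower, that 1 being SLT2, with 205 genes at an unadjusted p under 0.05. Targets of the cell wall integrity pathway, in which Slt2 acts, were lower as a list, with a median of -0.13 and 16 of 20 below 0 (camera adjusted p = 0.00706, and 0.929 with an estimated correlation). Adjusted over the list alone 1 member was called lower, the wall mannoprotein gene CWP1, at 11.95 ± 0.96 in wild type and 9.81 ± 0.28 in slt2 (log2 fold change -2.14, SE 0.44, adjusted p = 0.629 over all genes). It is named after its values were seen, as are the next 3 genes. PRM5 was at 9.06 ± 0.62 in wild type and 7.36 ± 0.29 in slt2, SRL3 at 8.44 ± 0.18 and 7.19 ± 0.27, and the Slt2-like kinase gene KDX1 at 6.58 ± 0.49 and 5.82 ± 0.23. Without the 3 wild-type arrays that stood apart, PRM5 was called as well (log2 fold change -2.05, adjusted p = 0.0266), while the camera adjusted p of the list was 0.161 with the median at -0.13.

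Other lists also set the untreated genotypes apart. Iron (median 0.34), phosphate (0.35), ribosome biogenesis (0.31), amino acid synthesis (0.10) and cell separation genes (0.19) were higher in slt2 (camera adjusted p = 0.000145, 0.000189, 0.000189, 0.00752 and 0.000936). Amino acid synthesis no longer passed with quantile normalization (adjusted p = 0.128). Respiratory genes (-0.48) and general stress genes (-0.42) were lower (adjusted p = 1e-06 and 0.00752). With an estimated correlation the adjusted p was 0.929 for all 28 lists. Wild-type untreated array 2 carried part of this: on it the median was -1.12 for iron, -0.92 for phosphate, -0.69 for ribosome biogenesis and 1.34 for general stress. Without the 3 wild-type arrays that stood apart, array 2 among them, medians were 0.05 for iron and 0.08 for phosphate and ribosome biogenesis. These were smaller but kept their sign, while that of general stress changed sign (0.04). Respiration stayed at -0.44, cell separation went to 0.28 and amino acid synthesis to 0.04 in that run. Only sizes are given here, since that run has fewer arrays and its 1 wild-type arsenate array adds nothing to the estimate of spread. The other 20 lists, from oxidative stress (median 0.01, adjusted p = 0.659) to RNA polymerases I and III (0.20, 0.0624), did not pass. Among the scalings of the arrays, meiosis passed with quantile normalization (adjusted p = 0.0278) and not with centred arrays (0.141). Without the 3 wild-type arrays that stood apart, the meiosis median went from -0.17 to -0.36. In that run medians were 0.16 for a-cell genes, 0.07 for late G1, 0.05 for glycolysis and 0.02 for ribosomal proteins. With all arrays these were 0.11, 0.08, 0.03 and 0.04. Of the unfolded protein response genes 1 was lower adjusted over the list alone, and the medians of 7 of these 20 lists changed sign with the scaling. Groups did not overlap for 26.8% of genes, where chance gives 10% for groups of equal spread. The median SD was 0.21 in wild type and 0.08 in slt2. Unequal spread can raise the share given by chance, to an extent not computed here. The genotypes' values differ in printed digits and a shared RMA run is not stated. Offsets between the genotypes thus cannot be told apart from a genotype effect.

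The fourth comparison set the genotypes side by side after arsenate. SLT2 was lower in slt2 (log2 fold change -5.41, SE 0.18, adjusted p = 1.73e-07), and since its signal there was close to the background the size of this difference, as of the one without arsenate, is poorly resolved. PRM7, a pheromone-regulated membrane protein gene, was higher, at 10.87 ± 0.43 in slt2 against 8.01 ± 0.46 in wild type (log2 fold change 2.86, SE 0.30, adjusted p = 0.00677, higher in 3 of 3 arrays). These were the only calls by limma, 1 higher and 1 lower, with 1796 genes at an unadjusted p under 0.05. The targets of the cell wall integrity pathway were lower in slt2 as a list, with a median of -0.36 (camera adjusted p = 0.00596, and 0.72 with an estimated correlation). This was the 1 list to pass fry in this comparison (adjusted p = 0.0369), where camera passed 16. Of its genes 8 of 20 were lower adjusted over the list alone. This count does not compare the list with other genes. Over all 5449 genes, 1066 were lower at an unadjusted p under 0.05. Named after their values were seen, PRM5 was at 9.91 ± 1.08 in wild type and 7.30 ± 0.23 in slt2, SRL3 at 9.59 ± 1.27 and 7.23 ± 0.06, and CWP1 at 13.11 ± 0.31 and 10.84 ± 0.56. Over all genes their adjusted p was 0.142.

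Lists also set the genotypes apart after arsenate. General stress genes (median -2.38), glucose-repressed genes (-1.88), respiratory genes (-0.94), tricarboxylic acid cycle genes (-0.54), heat shock genes (-0.46) and meiosis genes (-0.44) were lower in slt2 (adjusted p from 2.89e-10 to 0.0286). Ribosome biogenesis (1.65), RNA polymerases I and III (1.13), ribosomal proteins (0.79), amino acid synthesis (0.76), late G1 genes (0.55) and ergosterol genes (0.43) were higher (adjusted p from 4.91e-16 to 0.00596), as were the phosphate (0.87), arsenic (0.65) and sulfur lists (0.43; adjusted p = 0.00104, 0.0108 and 0.0286). Adjusted over the list alone, 27 of 31 general stress genes and 32 of 35 respiratory genes were lower, and of 16 phosphate genes 10 were higher and 1 lower. For comparison, 730 of all 5449 genes were higher and 1066 lower at an unadjusted p under 0.05. Of 28 oxidative stress genes 3 were higher and 5 lower, and 1 or 2 genes were lower in the sulfur, pathway component, pheromone, unfolded protein response, a-cell, alpha-cell and meiosis lists. With an estimated correlation the smallest adjusted p was 0.72, and without the 3 wild-type arrays that stood apart 4 lists passed: ribosome biogenesis (median 0.24), phosphate (0.34), RNA polymerases I and III (0.12) and amino acid synthesis (0.07). The medians of sulfur, ribosomal protein, ergosterol and late G1 genes, 4 of the 16 lists that had passed, changed sign in that run. Those of general stress (-0.21, adjusted p = 0.109), the cell wall integrity targets (-0.13, 0.0512), respiration (-0.21, 0.0646), meiosis (-0.24, 0.163), the tricarboxylic acid cycle, glucose-repressed genes (each -0.07), heat shock (-0.06) and arsenic genes (0.06) kept their sign and did not pass. The other 12 lists, from oxidative stress (-0.26, adjusted p = 0.34) to cell wall synthesis (0.18, 0.0592), did not pass. Cell wall synthesis passed with centred arrays only and the proteasome with quantile normalization only (adjusted p = 0.0492 and 0.0431).

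The PRM7 call was lost under 5 alternatives, among them the model on the 6 arsenate arrays, array weights, 1 weight per group and the run without the 3 arrays that stood apart (adjusted p = 0.365, 0.999, 0.264 and 0.114, in a range from 0.00183 to 0.999), and the SLT2 call with array weights and 1 weight per group (0.216 and 0.0505, in a range from 1.32e-07 to 0.216). Without wild-type arsenate array 3, 1123 genes were higher and 1201 lower, without wild-type untreated array 1 or slt2 arsenate array 3 there were 2 higher, and without wild-type arsenate array 1 there were 2 lower. On simulated data with each group's own spread and noise independent between genes, 59.8% of the calls of this comparison were false. The simulation made 368 calls where the data gave 2, so this share need not hold for the data. The genotype effects without and with arsenate correlated across genes at r = 0.686 (rho 0.719, SLT2 left out). Groups did not overlap for 40.1% of genes after arsenate, where chance gives 10% for groups of equal spread. The median SD was 0.49 in wild type and 0.07 in slt2, so the share given by chance may be higher. The open question of a shared RMA run holds here too.

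The last comparison asked whether arsenate changed transcripts differently in slt2 and in wild type. Limma called 0 genes higher and 0 lower, with 28 at an unadjusted p under 0.05 and a smallest adjusted p of 0.711. ARR2, ARR3, FRM2 and the other genes called in slt2 were thus not shown to respond differently in wild type. The 5 genes with the smallest p, none past the threshold, were PRM7 (difference 2.28, SE 0.42), YGR035C (2.25, SE 0.64), FRE7 (-2.57, SE 0.76), YNL146C-A (-0.74, SE 0.22) and REE1 (-0.78, SE 0.24), each with an adjusted p of 0.711. As lists, 10 shifted up and 9 down by camera, led by ribosome biogenesis (1.35) and RNA polymerases I and III (1.04) upward and glucose-repressed (-1.74) and general stress genes (-1.46) downward. Without the 3 wild-type arrays that stood apart these medians were 0.17, 0.11, 0.10 and -0.21, and 9 of the 19 had changed sign, that of glucose-repressed genes among them. None passed with an estimated correlation (smallest adjusted p = 0.519). The cell wall integrity targets did not pass (median -0.22, adjusted p = 0.0574). In simulated data with each group's own spread, 33% of genes differing by 1 log2 unit and 74% of those differing by 2 were recovered. Of the calls in that simulation 30.5% were false. Its noise was independent between genes and it made 154 calls where the data gave 0, so these shares need not hold for the data. Without wild-type arsenate array 3 this comparison called 5 genes higher and 17 lower.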

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

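The counts of other splits and the test of the cell wall targets without 3 wild-type arrays were set before their results were seen, and the tests of mislabelling, a common response, glucose exhaustion, shared preparation, RNA quality and separate runs were chosen after.

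The arsenate effect differed between slt2 and wild type in 19 of 28 lists by camera on the difference itself, and in 0 with an estimated correlation (smallest adjusted p = 0.519). The median difference, slt2 minus wild type, was positive for ribosome biogenesis (1.35, camera adjusted p = 3.13e-16), RNA polymerases I and III (1.04, 6.69e-07), cytosolic ribosomal proteins (0.75, 2.2e-16), amino acid synthesis (0.62, 4.64e-08), arsenic handling (0.52, 0.00697) and late G1 genes (0.47, 0.0302). It was also positive for phosphate (0.40, 0.0436), ergosterol (0.32, 0.000638), sulfur (0.30, 0.00188) and cell wall synthesis (0.26, 0.0302). It was negative for glucose-repressed genes (-1.74, 0.000136), general stress (-1.46, 1.56e-09), respiration (-0.52, 3.09e-07), the tricarboxylic acid cycle (-0.46, 0.00122), cell separation (-0.39, 0.00155), heat shock (-0.36, 0.00088), iron (-0.34, 0.0178), meiosis (-0.30, 0.00675) and the proteasome (-0.10, 0.0257). Cell wall synthesis and meiosis did not pass with quantile normalization (adjusted p = 0.0539 and 0.104). Without the 3 wild-type arrays that stood apart, 9 of the 19 medians changed sign. Those of glucose-repressed genes (0.10), respiration (0.20), the tricarboxylic acid cycle (0.08), iron (0.12) and meiosis (0.22) came to lie above 0. Those of late G1 (-0.22), ergosterol (-0.02), ribosomal proteins (-0.02) and cell wall synthesis (just below 0) came to lie below it. The other 10 kept their sign and were smaller. Those below 0 were general stress (-0.21), cell separation (-0.18), heat shock (-0.04) and the proteasome (-0.04). Those above 0 were ribosome biogenesis (0.17), arsenic (0.13), phosphate (0.13), sulfur (0.12), RNA polymerases I and III (0.11) and amino acid synthesis (0.03). For amino acid synthesis and iron, camera's direction in that run was down, against the sign of the median.

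For 4 of the genes named in the results every arsenate array moved one way against its untreated mean in wild type and the other way in slt2. Over all 5449 genes 129 did so (2.37%), where 476 would if the genotypes were independent, and 1038 moved the same way. Opposite moves were thus rarer than independence gives. The 4 genes were named for the small p of their difference, so their pattern adds no separate evidence. The difference was 2.28 for PRM7, -2.57 for FRE7, -0.74 for YNL146C-A and -0.78 for REE1, and the test of the difference did not pass for any of them (adjusted p = 0.711). A reporter probe set, outside the genes tested, was 8.74 log2 units higher in untreated slt2 than in untreated wild type (adjusted p = 2.39e-05). It lay between 14.15 and 14.24 on the 6 slt2 arrays and between 4.91 and 8.83 on the 6 wild-type arrays. In wild type it was higher on each arsenate array (6.48 to 8.83) than on any untreated one (4.91 to 6.19). That change did not pass (log2 fold change 2.18, adjusted p = 0.301). After arsenate the probe set was 6.56 higher in slt2 than in wild type (adjusted p = 0.000376). Its untreated wild-type values, 4.91 to 6.19, were near the level of deleted genes, and the highest signals of the arrays were 14.82 to 14.91, so the size of the difference is poorly resolved at both ends. What the probe set detects was not examined here. Groups of 3 are too small to test a single array as an outlier.

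Wild-type arsenate array 1 stood apart from the other 11 arrays, with glucose-repressed genes 5.24 log2 units above the untreated mean. An untreated culture under an arsenate label is argued against: the smaller of the gaps of ARR2 and ARR3 to the highest untreated array was 4.70. The rise of the glucose-repressed genes was not common to the wild-type arsenate arrays, as the higher median of the other 2 was 0.37. This restates that array 1 stood apart and does not test a cause. A culture past glucose exhaustion stays open: the glucose-repressed median lay at percentile 100 of matched random lists and the ribosome biogenesis median, -3.45, at percentile 0, but these values describe the pattern and do not test its cause. A stronger arsenate response of this 1 culture stays open as untested.

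The wild-type arrays numbered 2, untreated and with arsenate, shared a deviation from the other arrays of their groups. Of 372 genes more than 1 log2 unit away in the untreated array, 343 (92.2%) went the same way in the arsenate array compared with arsenate array 3. A shared culture or preparation of these arrays stays open, since this share describes the pattern and does not test its cause. Loss of 5' signal through RNA quality alone stays open. The general stress medians of 1.34 and 2.21 lay at percentile 100 of random lists matched on gene length and expression in both arrays. But the test was chosen after this shift was seen, so the percentile restates it. The mean 3' minus 5' signal was raised on these 2 arrays, at 1.59 and 1.79, against at most 1.18 on the others. No group of the design gives a biological explanation, and none was tested.

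Targets of the cell wall integrity pathway were lower in slt2 in both genotype comparisons, with medians of -0.13 and -0.36. Separate summarisation of the genotypes stays open: the higher of the percentiles among matched random lists was 1.11, but this restates the shift, and camera with an estimated correlation did not pass (adjusted p = 0.929 and 0.72). Wild-type arrays that stood apart stay open as a cause: without them the camera p of the untreated comparison was 0.0921, which met the bound for a cause set beforehand, but the median was -0.13 with and without them and fewer arrays were compared, so the test decides nothing. In the arsenate comparison, which this test did not cover, the median went from -0.36 to -0.13 without them (adjusted p = 0.0512). Loss of Slt2 kinase activity stays among the open explanations, as untested.

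With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In wild type the real split called 1 gene and the highest other 775, and 3 of the 10 splits called as many as the real one, which points to a structure among the wild-type arrays. For the lists this was 17 against 18, with 5 of 10 splits as large. In slt2 the 12-array model called 2 genes against 0 in the highest other split, with 1 of 10 splits as large, the real one, and 10 lists against 15, with 5 as large. In the slt2 arrays alone the counts were 134 genes against 0, with 1 of 10 as large, and 12 lists against 15, with 3 as large. Untreated genotypes gave 1 gene against 0, with 1 of 10 as large, and 8 lists against 16, with 9 as large. Genotypes after arsenate gave 2 genes against 0, with 1 of 10 as large, and 16 lists against 20, with 6 as large. For the difference of effects 100 splits were counted. All 100 gave at least the 0 genes of the real split, which had to be so and tests nothing (highest other 10). For its lists chance was not excluded, as 6 of 100 gave at least the real 19 (highest other 20).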

How the results depend on the processing

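The weight per group, the run without the 3 wild-type arrays that stood apart and the alternatives to the slt2-only fit were chosen after the results were seen, and the other alternatives before. The cause of a change was not tested unless it is given here. Of the values of named genes in the 12-array model, 924 kept direction and side of the threshold, 14 came to pass it and 17 ceased to; in the slt2 arrays alone 549 kept both and 113 ceased to pass. Of the 45 named genes called there, 26 lost their call with the replicate block, 1 with quantile normalization and 6 to 21 when an array was left out. Deleted genes lay at up to 5.47 (LEU2), and their level differed between probe sets (URA3 at up to 4.55). Falls near these levels are thus poorly resolved.

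In wild type 0 genes were higher in the model of 2 groups, 0 with 1 weight per group, 0 without the dimmest 20% of probe sets, which removes ARR2, 2 with the replicate block, 2 with array weights and 3 without the 3 arrays. In slt2 there were 104 higher and 30 lower in the model of 2 groups, 169 and 45 with 1 weight per group, 663 and 569 with array weights, and 43 and 6 without the 3 wild-type arrays. There was 1 higher without the dimmest 20%, which removes ARR2, and 1 at an adjusted p of 0.01. The weight per group was 0.617 and 0.0934 for the wild-type groups and 3.37 and 5.15 for the slt2 groups. These models called 112 (weight per group) and 134 (array weights) of the 134 genes of the slt2 arrays alone. The array weights did not converge and put 1.15e-08 on wild-type arsenate array 2. For untreated genotypes there were 267 higher and 688 lower with array weights, 2 lower without the 3 arrays, and 0 lower without the dimmest 20%, which removes SLT2. For genotypes after arsenate there were 0 higher in the model of 2 groups, with the replicate block, with array weights, with 1 weight per group and without the 3 arrays, and 2 with all probe sets. Those 2 were probe sets, that of PRM7 (log2 fold change 2.86) and 1 other (3.18). PRM7 has 2 probe sets, and their mean gave 3.02. There were 0 lower with array weights, with 1 weight per group, and without the dimmest 20%, which removes SLT2.

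In the slt2 arrays alone there were 23 higher and 5 lower with the replicate block, 285 and 126 with a trended and robust prior, 158 and 84 with centred arrays, 184 and 157 with quantile normalization, and 22 and 10 at an adjusted p of 0.01. Replicate numbers were not taken to pair the arrays, since not every same-number pair correlated above 0.1: the deviations from group means of untreated and arsenate arrays of the same number correlated across genes at 0.04, 0.35 and 0.47 in wild type and 0.39, 0.05 and 0.23 in slt2. As a hint from the data, 4 of the 6 untreated arrays correlated best with the arsenate array of their own number. With an estimated correlation camera passed 1 list in slt2 in the 12-array model, and 0 in each other comparison and in the slt2 arrays alone. By fry the lists past the threshold were 1 in wild type, 0 in slt2 and 0 for the difference. For the genotypes fry passed 0 untreated and 1 after arsenate, and in the slt2 arrays alone 3. For genotypes after arsenate 10 lists passed without the dimmest 20% and 4 without the 3 arrays. The correlation of arsenate effects was 0.684 without the 3 arrays. The genes that fell in slt2 had a mean in wild type of 0.20 in the model of 2 groups (p = 0.0586), 0.15 with quantile normalization (p = 0.0863), 0.20 with an estimated correlation (p = 0.182), and, with the sign reversed, -0.25 without the 3 arrays, where the 1 wild-type arsenate array left is assumed to vary like the other groups. Among unadjusted p under 0.05 the share of rises was 72.8% in wild type (65.6% centred, 55.1% quantile), 88.7% in slt2 (72% and 70.4%), 27.3% for untreated genotypes (58.6% and 57.6%) and 50% for the difference (34.2% and 58.6%).

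With each array left out in turn, wild type had 1 to 812 higher and 0 to 796 lower, both highest without wild-type arsenate array 3. In slt2 1 to 6 were higher, with 6 without wild-type arsenate array 1, 5 without arsenate array 3 and 1 without wild-type untreated array 1 or 3, slt2 untreated array 1, 2 or 3 or slt2 arsenate array 1 or 2. Genotypes after arsenate had 1 to 1123 higher and 1 to 1201 lower, and the difference 0 to 5 higher and 0 to 17 lower, each highest without wild-type arsenate array 3. The slt2 arrays alone had 32 to 73 higher and 9 to 40 lower, lowest without slt2 untreated array 3, and 9 lower also without arsenate array 1. The mean in wild type of genes that fell in slt2 went from 0.0447 without wild-type untreated array 1 to 0.456 without arsenate array 3. Their camera test ceased to pass without that arsenate array and without untreated array 2 or 3 (mean 0.27 each). A left-out array also shrinks its group to 2.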

Other observations

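All tests in this part were chosen after the results were seen. The p-values of the zinc and the one-carbon and purine lists on the slt2 arrays therefore restate that choice.

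Of 14 genes under the zinc regulator Zap1, 5 rose in the slt2 arrays with arsenate, 12 were above 0, and the list median was 0.12 (camera p = 6.32e-05, and 0.2 with an estimated correlation). The 5 were ZPS1 (log2 fold change 2.65), the zinc transporter genes ZRT1 (1.02), ZRT2 (0.50) and ZRT3 (0.41), and ZAP1 (0.96). A zinc response to arsenate may be shared by wild type, but the camera p there was 0.967 with a median of 0.23 and direction down, so the test leaves it open. Wild-type untreated and arsenate arrays 2 had zinc list medians of 1.12 and 1.39, so the wild-type arrays spread widely in this list.

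Of 13 genes of one-carbon metabolism and purine synthesis, 7 rose in the same arrays, 13 were above 0, and the list median was 0.50 (camera p = 3.84e-12, and 0.059 with an estimated correlation). The 7 were ADE17 (log2 fold change 1.07), GCV1 (adjusted p = 0.0268), ADE1 (0.68), ADE4 (0.51), GCV2 (0.50), ADE12 (0.45) and GCV3 (0.40). In the wild-type arrays, which are separate samples, the list had a median of 0.42 with 11 of 13 above 0 (camera p = 0.000345, and 0.105 with an estimated correlation). In the 12-array model the list in slt2 had a camera p = 3.47e-27, and 0.000547 with an estimated correlation. A response to arsenate in both genotypes is a hypothesis, for which only the wild-type arrays give values separate from the choice of the list. With an estimated correlation the list passed in slt2 in the 12-array model, and neither in the slt2 arrays alone nor in wild type. GCV1 and ADE17 did not pass in wild type (log2 fold changes 1.43 and 0.95, adjusted p = 0.299).

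Genes raised at low oxygen had their highest median on wild-type untreated array 2, where it was 1.0, against at most 0.09 on the other 11 arrays and -0.53 on wild-type arsenate array 1. Over the wild-type arsenate comparison their camera p was 0.0543.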
